A study of Sus scrofa with 9 samples.

How the data were processed

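The samples were 9 RNA preparations of IPEC-J2, an epithelial cell line derived from the jejunum of a newborn pig, each hybridised to 1 Affymetrix porcine expression array as biotin-labelled cRNA. Per the labels' protocols, confluent monolayers were exposed to Salmonella enterica serovar Typhimurium for 1 h, washed, and kept in medium with 50 ug/ml gentamicin, an antibiotic that does not enter cells, until 2 h or 4 h. The control cultures received medium alone and carry the time 0 h. The titles of all 3 controls, and of no infected array, have a letter b after the replicate number, whose meaning is not given in the sources used here. Each of the 3 groups held 3 arrays. The labels call the experiment triplicate without saying whether the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

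The deposited values were on the log2 scale and had been made by the authors with RMA in R 2.7.0, per the submitters' processing notes. RMA corrects background, makes the distributions of the arrays alike and summarises the probes of a probe set, so a change shared by most transcripts cannot be seen in its values. Which arrays had been normalised together was not given in the sources used here. The medians of the 9 arrays lay between 6.18 and 6.21. No scanner intensities were used here. The number of arrays limits the precision.

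The table held 24123 probe sets. The 124 control probe sets of the manufacturer were left out, and 23999 were tested. Gene names came from the platform annotation through Entrez identifiers, of which 10187 of 10297 annotated probe sets had one in the RefSeq gene table. One gene symbol was given for 10110 tested probe sets, several for 157 and none for 13732, and the single symbols covered 6790 genes. No gene was named from a probe set with several symbols or none. Where a gene had several probe sets, the one with the highest mean log2 value over all 9 arrays stood for it.

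Differences were tested with limma 3.58.1 in R 4.3.3, with one linear model over the 9 arrays, the contrasts 2 h minus control, 4 h minus control and 4 h minus 2 h, and empirical Bayes moderation (6 residual and 4.19 prior degrees of freedom). All such p-values are two-sided and Benjamini-Hochberg adjusted over the 23999 probe sets, and a probe set was called at an adjusted p under 0.05. A moderated F test asked for any difference among the 3 groups. Camera from the same package, with a preset correlation of 0.01 between genes, tested 27 gene lists per contrast, each with at least 5 measured genes, with adjustment over the 27 lists. The lists covered NF-kB targets, cytokines and chemokines, immediate early genes, interferon-stimulated genes, pattern recognition, antimicrobial defence, growth factors and repair, unfolded protein and integrated stress response, heat shock, cholesterol synthesis, hypoxia and glycolysis, S phase, mitosis, cell junctions, autophagy and lysosome, cell death, p53 targets, oxidative stress, enterocyte differentiation, circadian clock, glucocorticoid response, ribosomal proteins, oxidative phosphorylation, and markers of fibroblasts, leukocytes and endothelium, and 1 further list is not reported here. Older symbols of the annotation were matched for 12 list genes after the data were examined. Camera was repeated with a correlation estimated per list, and with fry.

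The design, the gene lists and the rule for named genes were fixed before the data were examined. The rule took, among called genes whose groups did not overlap, the 8 largest rises and the 8 largest falls at 2 h and at 4 h, and the 5 largest each way for 4 h against 2 h. Where none passed in a direction it took the 5 genes of smallest p. It always took CXCL8, CXCL2, TNF, NFKBIA and 2 genes that no symbol of the array matched, CCL20 and TNFAIP3. It added up to 4 members per list with the smallest p. Genes named outside it are said to be so.

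The 2 h and 4 h comparisons share the control arrays. Their overlap is given beside the overlap of independent lists and beside 50 simulations of unchanged groups that share controls. The simulations drew the control arrays afresh as well, rather than using the measured ones. The 3 control arrays are too few to be split. Replicate numbers were checked for pairing through the correlation of deviations from group means over all tested probe sets. Same-numbered 2 h and control arrays had correlations of 0.28, 0.28 and 0.25, so the numbers were taken to pair these groups. With the replicate number as a block in the linear model, 24 probe sets were called at 2 h in place of 22. The changes, SEs and p-values given in the Results come from the model without the block.

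The test was tried on simulated data of 23999 probe sets for the 2 h comparison, with 200 changed in each of 10 sets. It recovered 81.5% of changes of 0.5 on the log2 scale, 99.6% of changes of 1 and 100% of changes of 2, with 5.52% false among the calls, and it made 0 calls where nothing changed. These shares hold for 200 changed probe sets. In the data only 22 were called at 2 h, which makes the adjusted threshold stricter, and the smallest change called was 0.57. Recovery in the data may therefore be lower. The list test found a list shifted by 0.5 in 10 of 10 simulated sets. Genes were drawn independently there, so this does not show how the list test behaves where genes move together.

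The alternatives were the replicate block, a filter on dim probe sets, another prior variance, array weights, renewed quantile normalisation, median centring, 1 probe set per gene, stricter thresholds, only the arrays compared, other list tests, other probe sets of a gene, and leaving out each array in turn.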

Results

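Transcript levels were measured in IPEC-J2 cells, which grow as a polarised sheet like the lining of the small intestine, before and after exposure to Salmonella Typhimurium, a bacterium that enters gut epithelial cells. There were 3 uninfected arrays at 0 h, 3 at 2 h and 3 at 4 h. All pairs of arrays correlated closely, and the first principal component held 25.4% of the variance. The controls lay at -14.7, -8.66 and -14.0 on it, the 2 h arrays at 3.69, 9.38 and -2.42, and the 4 h arrays at -1.78, 13.9 and 14.6. No uninfected arrays at 2 h or 4 h were analysed here, so each comparison with the control holds exposure, elapsed time and gentamicin together. Control replicate 3 stood apart in its hybridisation spikes, which had a mean log2 value of 8.79 against 10.0 and 9.91 on the other controls, and on the second principal component, with 20.3% of the variance, where it lay at -16.5 against 6.87 and 6.36.

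The first comparison asked which transcripts had changed by 2 h. IL1A, an alarm cytokine of epithelial cells, rose by 3.32 ± 0.11 on the log2 scale (SE, n = 3 per group, adjusted p = 4.1e-07), which is 9.96-fold. The neutrophil-attracting chemokines CXCL2 and CXCL8 rose by 2.92 ± 0.15 and 2.04 ± 0.13 (adjusted p = 1.4e-05 and 4.5e-05). CXCL8 is the cytokine whose protein the study measured in the culture medium as its check of activation. The transcription factor IRF1 rose by 2.00 ± 0.17 and NFKBIA, the inhibitor that restrains NF-kB, by 1.75 ± 0.09. SNAI1, a repressor of epithelial genes, rose by 1.36 ± 0.16, IL6 by 0.90 ± 0.10 and PLET1 by 0.86 ± 0.09. CFTR, the chloride channel of crypt cells, rose by 0.57 ± 0.06 (adjusted p = 0.0063). It kept the call under 14 of 15 alternatives. These did not include the filter on dim probe sets, which removed its probe set, at percentile 38.0 of mean level. A second, similarly dim probe set of PLET1 gave -0.07. The other probe set of SNAI1 gave 0.88 (adjusted p = 0.011). CEBPD, a transcription factor of the acute phase, was called on a probe set that was not its brightest, at 0.93 ± 0.13 (adjusted p = 0.042), while the brightest gave 0.74 (adjusted p = 0.057).

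Of the 23999 probe sets, 22 rose and 0 fell at 2 h by limma. At an unadjusted p under 0.05 there were 779 higher and 759 lower, where chance gives 1200 in all. Of the 22, 12 had a symbol, covering 10 genes, and 10 had none. Over all probe sets, 8.98% had groups that did not overlap, and chance gives 10%. None of the falls passed the threshold: the smallest p-values belonged to FRS2 at -0.27, VRK3 at -0.26, NUDT6 at -0.34, LACTB at -0.27 and CYP1A1 at -0.43, with adjusted p between 0.48 and 0.66. The largest rise of all, chosen after its value was seen, belonged to a probe set with no symbol, at 4.80 ± 0.19, and another such probe set rose by 3.32 ± 0.21. SNAI1 lost its call without control replicate 1, at 1.25, and without control replicate 2, at 1.38. The GAPDH 3' minus 5' difference, a sign of RNA integrity, had a mean log2 value of 0.32 ± 0.05 in the controls and 0.19 ± 0.06 at 2 h, and the poly-A spikes, added before labelling, 6.20 ± 0.02 and 6.28 ± 0.06 (SD, n = 3, exact permutation p = 0.1 for each, two-sided, the smallest this design allows).

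Among the gene lists, the 24 measured cytokines and chemokines shifted up at 2 h (camera adjusted p = 3.1e-10). Of these, 4 rose over all probe sets and 6 adjusted over the list alone. The 11 measured NF-kB targets also shifted up (adjusted p = 3.0e-08), with 2 risen over all probe sets and 3 adjusted over the list alone, ICAM1 at 0.72 among the latter. Both calls held with an estimated correlation, each at adjusted p = 0.0458. TNF, a cytokine at the head of NF-kB signalling, stood at 0.42 ± 0.08 and did not pass over all probe sets (adjusted p = 0.17), although it did without 2 h replicate 3, at 0.50. The 18 immediate early genes, which respond within minutes to growth and stress signals, were called up (adjusted p = 0.0271), but with an estimated correlation the adjusted p was 0.932. Of them 0 passed over all probe sets and 2 adjusted over the list alone, ZFP36 at 0.51 and BTG2 at 0.67, both named after their values were seen. The 11 S phase genes were called up (adjusted p = 0.0085) with 0 members past either threshold, and an adjusted p of 0.950 with an estimated correlation. Without control replicate 3 the calls of these last lists ended, both at adjusted p = 0.0884. The immediate early call also ended without control replicate 2 at 0.0562, 2 h replicate 2 at 0.0657, 2 h replicate 3 at 0.608 and 4 h replicate 1 at 0.0566, and the S phase call without 2 h replicate 1 at 0.708.

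**Figure D1:**
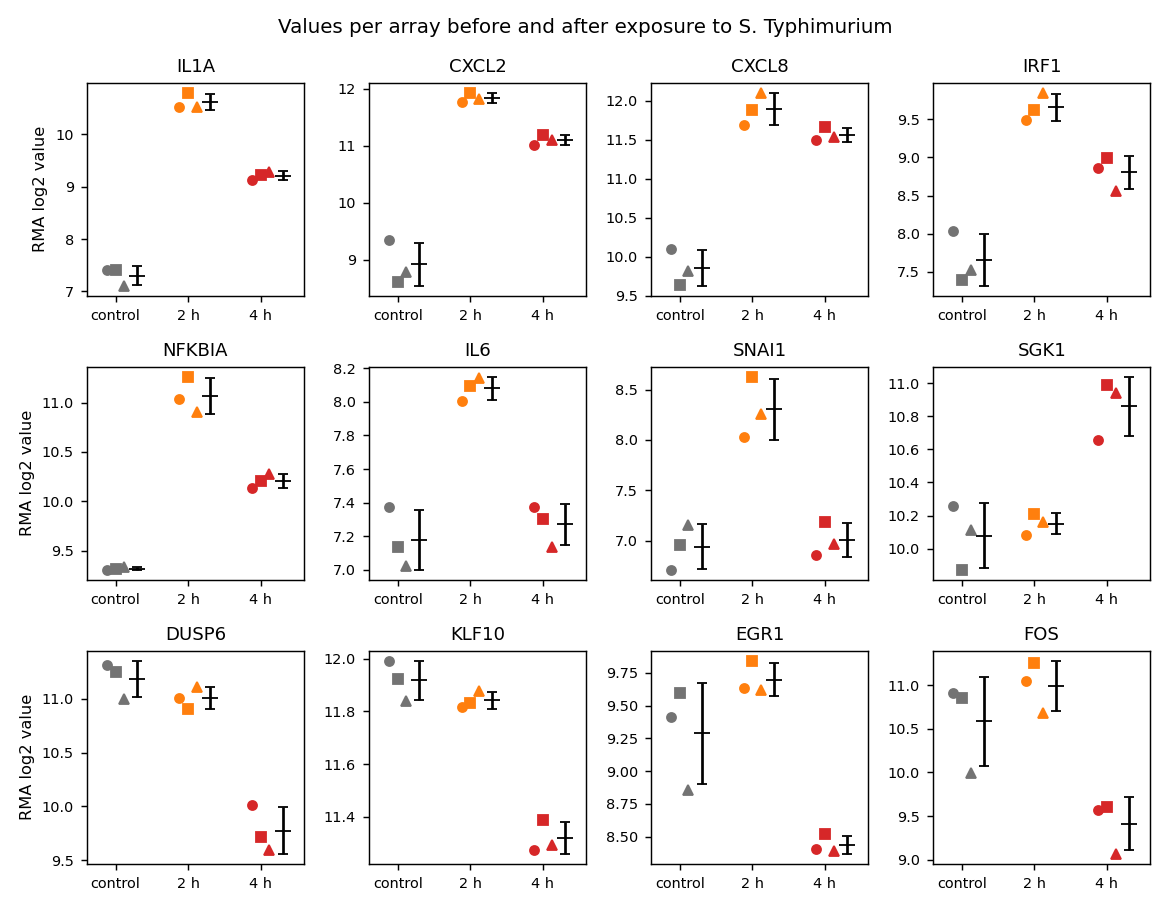
RMA log2 value (vertical axis, own scale per gene) of 12 genes on each array of the control, 2 h and 4 h groups; circles, squares and triangles are replicates 1, 2 and 3, and bars beside them give mean ± SD of 3 arrays. IL1A means ran from 7.30 in the control to 10.6 at 2 h and 9.21 at 4 h, and DUSP6 means from 11.2 in the control to 9.78 at 4 h.

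The next comparison set 4 h against the control. The inflammatory genes were still raised: CXCL2 by 2.19 ± 0.15, IL1A by 1.91 ± 0.11, CXCL8 by 1.71 ± 0.13, IRF1 by 1.15 ± 0.17 and NFKBIA by 0.89 ± 0.09 (adjusted p from 5.1e-05 to 0.024). PLET1 rose by 0.99 ± 0.09, with its other probe set at -0.22. ICAM1, an adhesion molecule for leukocytes, rose by 0.85 ± 0.12 and SGK1, a kinase of sodium transport, by 0.78 ± 0.11. CEBPD rose by 0.77 ± 0.11, and its other probe sets gave 1.00 (adjusted p = 0.017) and, the dimmest, 0.55 (adjusted p = 0.13). GPX1, which reduces peroxides, rose by 0.49 ± 0.08. IL6 and SNAI1 stood at 0.09 and 0.06 against the control (adjusted p = 0.76 and 0.92).

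Falls past the threshold appeared at this time. DUSP6, a phosphatase that restrains the kinase ERK, fell by 1.41 ± 0.12 on the log2 scale (adjusted p = 6.4e-04), and its other probe set gave -0.87 with an adjusted p of 0.12. KLF10 fell by 0.60 ± 0.06 and MSANTD4 by 0.52 ± 0.08. TSC22D3, a glucocorticoid-induced gene, fell by 0.48 ± 0.08, while its other, dimmer probe set gave -0.13 (adjusted p = 0.59). BANP fell by 0.45 ± 0.06. EGR1, an immediate early transcription factor, gave -0.85 on its brightest probe set (adjusted p = 0.071) and -1.39 and -1.24 on the others, both past the threshold. Without control replicate 3 the brightest passed too, at -1.07, as did FOS at -1.47. A probe set with no symbol, chosen after its value was seen, fell by 1.55.

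In all, 33 probe sets rose and 25 fell at 4 h by limma, covering 17 genes up and 6 down, while 31 had no symbol. Groups did not overlap for 16.0% of probe sets, where chance gives 10%. The count of 58 depended on single arrays: it was 19 without control replicate 1, 33 without control replicate 2, 33 without 2 h replicate 2, 155 without 4 h replicate 1, 27 without 4 h replicate 2 and 23 without 4 h replicate 3. It also depended on the model, with 109 under another prior variance and 256 with array weights. IRF1, ICAM1, SGK1, CEBPD, GPX1, MSANTD4, TSC22D3 and BANP each lost the call without at least 1 array, with unchanged direction. IRF1 then ranged from 1.03 to 1.35, ICAM1 from 0.78 to 0.99 and SGK1 from 0.68 to 0.88 over all alternatives. The poly-A spikes had a mean log2 value of 6.38 ± 0.09 at 4 h (exact permutation p = 0.1 against the controls) and the GAPDH difference was 0.19 ± 0.08 (exact permutation p = 0.2).

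The immediate early genes were the list with the largest median shift at 4 h, -0.35 over 18 genes (camera adjusted p = 1.4e-11, and adjusted p = 0.119 with an estimated correlation). DUSP6 and KLF10 fell over all probe sets and 11 genes fell adjusted over the list alone, FOS at -1.17 among them. NF-kB targets were called up (adjusted p = 1.6e-04, and 0.119 with an estimated correlation), with 3 risen over all probe sets and 5 adjusted over the list alone. Cytokines and chemokines were called up (adjusted p = 0.0044, and 0.409 with an estimated correlation), with 3 and 4 risen. The p53 targets were called down (adjusted p = 0.0044, and 0.119 with an estimated correlation). None of their 13 genes passed over all probe sets and 4 fell adjusted over the list alone, PLK3 at -0.55, GADD45A at -0.76 and CDKN1A at -0.39 among them. The 7 clock genes were called down (adjusted p = 0.0085, and 0.712 with an estimated correlation), where BHLHE40 at -0.61 passed adjusted over the list alone. S phase genes were called up (adjusted p = 0.0044, and 0.910 with an estimated correlation), with 2 risen adjusted over the list alone, MCM4 at 0.43 and FEN1 at 0.41. The S phase call ended without control replicate 3 at adjusted p = 0.0554 and without 4 h replicate 1 at 0.212, and the clock call without control replicate 2 at 0.106 and without 4 h replicate 1 at 0.132.

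**Figure D2:**
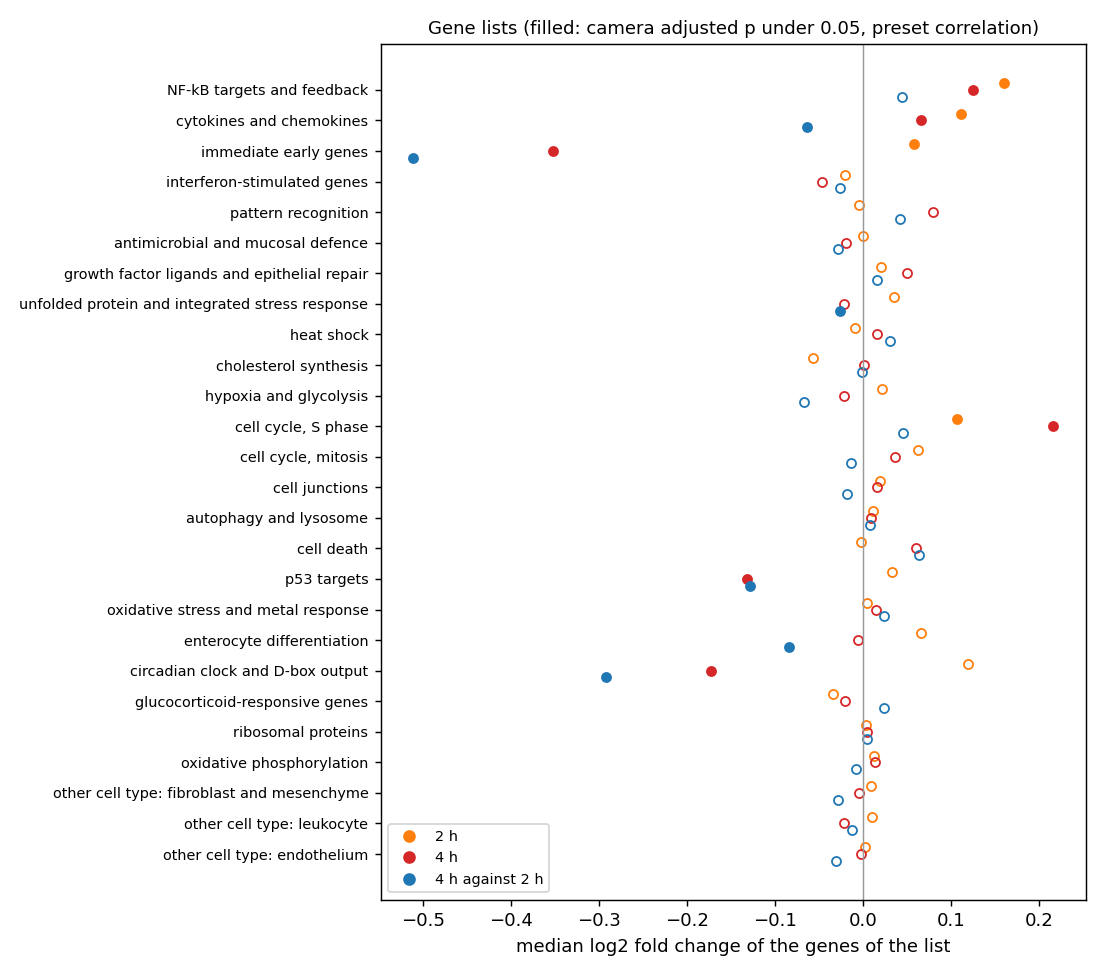
Median log2 fold change (horizontal axis) of the measured genes of each of 26 lists at 2 h, at 4 h and for 4 h against 2 h; filled circles passed camera with the preset correlation and open circles did not. Immediate early genes lay at 0.06 at 2 h, -0.35 at 4 h and -0.51 for 4 h against 2 h.

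The same rises were then followed from 2 h to 4 h. Of the 22 probe sets raised at 2 h, 15 were called up again at 4 h, and all 22 were above the control. Independent lists would share 0.0303. Simulated unchanged groups shared 0, but with nothing changed the test makes 0 calls, so this gives no chance level for the overlap. Part of the excess may come from the shared controls. Fold changes at the 2 times correlated at r = 0.602 across probe sets, which are not independent replicates, against 0.499 simulated, and their covariance was 0.0128 against 0.0048. The simulation gave all arrays the same spread and drew probe sets independently, which the measured arrays need not meet. These excesses too may therefore come in part from the control arrays.

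The direct test of 4 h against 2 h called 50 probe sets lower and 12 higher, while at an unadjusted p under 0.05 there were 915 lower and 1192 higher. IL1A fell by 1.41 ± 0.11 between the times (adjusted p = 0.0014), SNAI1 by 1.30 ± 0.16, NFKBIA by 0.86 ± 0.09 and IL6 by 0.81 ± 0.10. The other probe set of SNAI1 gave -0.65 (adjusted p = 0.047). CXCL2 at -0.74 and CXCL8 at -0.33 did not pass (adjusted p = 0.13 and 0.49). FOS fell by 1.58 ± 0.24, DDIT4, an inhibitor of mTOR, by 1.31 ± 0.19 and EGR1 by 1.26 ± 0.16. Of the 5 genes called higher, SGK1 rose by 0.71 ± 0.11, CLK1, a splicing kinase, by 0.49 ± 0.07 and GPX1 by 0.46 ± 0.08. The others, chosen after their values were seen, were called on a probe set that was not their brightest: KIAA1551 at 0.76 ± 0.11, with 0.37 on the brightest (adjusted p = 0.37), and PHF23 at 0.64 ± 0.10, with 0.61 on the brightest (adjusted p = 0.26). Groups did not overlap for 12.4% of probe sets, where chance gives 10%. The count of 62 was 40 without control replicate 1, 40 without control replicate 2, 10 without 2 h replicate 2, 41 without 2 h replicate 3, 35 without 4 h replicate 1, 32 without 4 h replicate 2 and 14 without 4 h replicate 3. Of these, 0 were higher without 2 h replicate 2 or without 4 h replicate 3, and 1 without control replicate 1 or without 4 h replicate 2. IL1A and NFKBIA kept the call without each array in turn, while SNAI1, IL6, FOS, DDIT4, EGR1, SGK1, CLK1 and GPX1 each lost it without at least 1, in the same direction.

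Between 2 h and 4 h, 6 lists were called down and 0 up. Immediate early genes had 6 members down over all probe sets and 13 adjusted over the list alone (median -0.51, adjusted p = 1.4e-18, and 0.0551 with an estimated correlation). In the stress response list (adjusted p = 0.0093, and 0.221 with an estimated correlation), DDIT3 at -0.92 and DDIT4 passed. Cytokines and chemokines (adjusted p = 0.0014, and 0.234 with an estimated correlation) had 2 down over all probe sets and 5 adjusted over the list alone. The p53 targets (adjusted p = 1.4e-04, and 0.0551 with an estimated correlation) had 0 and 4. For enterocyte genes (adjusted p = 0.0085, and 0.149 with an estimated correlation) only CFTR passed, at -0.45, and for clock genes (adjusted p = 1.4e-04, and 0.262 with an estimated correlation) only BHLHE40 over all probe sets, at -0.82, with its other probe set at -0.12. The stress response and enterocyte calls ended without 2 h replicate 3, both at adjusted p = 0.0540. The calls of DDIT3, CFTR and BHLHE40 each ended without at least 1 array, in the same direction. The F test over the 3 groups called 77 probe sets, and 31 without control replicate 1, 42 without control replicate 2, 26 without 2 h replicate 2, 41 without 4 h replicate 2 and 28 without 4 h replicate 3.

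A further 18 lists were not called in any comparison, with a lowest adjusted p of 0.176, for hypoxia and glycolysis. They included interferon-stimulated genes, pattern recognition, antimicrobial defence, cell junctions, cell death and oxidative phosphorylation. Markers of fibroblasts, leukocytes and endothelium had adjusted p of 0.493 or more. Median, mean and test pointed the same way for all 16 calls and differed in sign for 15 of the 62 others.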

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

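The tests of control replicate 3, of elapsed time, of the S phase list and of the spikes were chosen only after the results were seen. The change from control differed between 2 h and 4 h, by the limma test of the difference, for 18 of the named genes. It was lower at 4 h for FOS (-1.58), IL1A (-1.41), DDIT4 (-1.31), SNAI1 (-1.30), EGR1 (-1.26), DUSP6 (-1.23), HBEGF (-0.94), DDIT3 (-0.92), GADD45B (-0.92), NFKBIA (-0.86), BHLHE40 (-0.82), IL6 (-0.81), BANP (-0.58), KLF10 (-0.52) and CFTR (-0.45). It was higher for SGK1 (0.71), CLK1 (0.49) and GPX1 (0.46). The rule for named genes took part of these by this same test, so the count of 18 is partly set by the selection. Of the 18 calls, 3 were kept under all alternatives run. By camera, the lists differing between the times were immediate early genes (adjusted p = 1.43e-18), p53 targets and clock genes (both 1.38e-04), cytokines and chemokines (0.00141), enterocyte genes (0.00851) and the stress response list (0.00931), and none of these passed with an estimated correlation.

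The real grouping called 22, 58 and 62 probe sets at 2 h, at 4 h and between them, and of the 10 splits of the 6 arrays in each comparison 1, the real one, gave as many, with 0 as the highest of the others each time. It called 4, 6 and 6 lists, and 5, 2 and 5 of the 10 splits called as many, the highest of the others reaching 10, 8 and 12. With 10 splits the share cannot go under 0.05. For the F test, 1 of 100 splits drawn, the real one, gave as many as 77, with 32 the highest of the others. For the overlap 1 of 100, again the real one, gave as many as 15, with 9 the highest of the others. A random grouping of the arrays is thus unlikely for both. The splits moved arrays freely across replicate numbers, and they do not show how much of the overlap comes from the shared controls.

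The 25 probe sets below the control at 4 h had a median log2 change of -0.64, and of -0.09 at 2 h. A control level set by control replicate 3 was argued against as the whole cause by the calls made without that array. Without control replicate 3, 29 probe sets were called lower, 15 of them among the 25, against 5 without control replicate 1 and 16 without control replicate 2. The median of the 25 was -0.63 without control replicate 3, -0.61 without control replicate 1 and -0.65 without control replicate 2. These medians decide little, since the 25 were called with all 3 controls in the fit. Elapsed time and medium cannot be told apart from infection, since 0 uninfected arrays at 2 h or 4 h were analysed here. Lower output of the ERK kinase, which DUSP6 and EGR1 report on, may also contribute: of 29 ERK targets, listed after the falls had been seen but before the targets' own values were, only ETV5 (-0.30) and PHLDA2 (-0.11) were measured outside the other lists, and their camera p of 0.0770 on 2 genes decides nothing.

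The S phase list stood above the control at 2 h and 4 h, but its genes move together, with an estimated correlation of 0.742. Differences between single arrays may account for the call at 2 h: the lowest 2 h array minus the highest control was -0.0351, and the list mean was 9.16 on replicate 1 against 8.83 and 8.84 on the others. At 4 h the arrays, at 9.15, 8.96 and 8.91, all lay above the highest control at 8.86, the lowest by 0.0473, which is less than the range of the controls of 0.126, so the same explanation stays open there. A change of the cell cycle with infection stays open as untested.

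On control replicate 3 the 27 hybridisation spikes were lower than on the other controls by a median of -1.20, from -1.51 to -0.56. Less spike mix is consistent with the poly-A spikes, whose median difference was 0.0124. It leaves the 28S ribosomal probe open, at 7.81 on this array against 9.11 and 9.28. No biological explanation was tested.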

How the results depend on the processing

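The rises of IL1A, CXCL2, CXCL8 and NFKBIA at 2 h and at 4 h, of IRF1 and IL6 at 2 h, and the fall of KLF10 at 4 h kept direction and call under all alternatives run, and so did IL1A, NFKBIA and BANP for 4 h against 2 h. These are 14 of 42 calls of named genes. The others lost the call under at least 1 alternative, mostly with fewer arrays: 16 of 42 were lost with only the 6 arrays compared, 22 without 4 h replicate 3, 21 without 2 h replicate 2, 15 without 4 h replicate 2, 14 without control replicate 2, 12 without control replicate 1, 9 each without 2 h replicate 1 and 2 h replicate 3, and 8 each without control replicate 3 and 4 h replicate 1. Of the 16 list calls, 2 kept direction and call throughout, NF-kB targets and cytokines at 2 h.

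At 2 h the 22 probe sets became 11 with 1 probe set per gene and 13 at a log2 change of at least 1, and 16 to 25 with each array left out. At 4 h the 58 became 109 with another prior variance, 256 with array weights, 22 with 1 probe set per gene, 21 at adjusted p under 0.01, 20 at a log2 change of at least 1, 26 with only the arrays compared, and 19 to 155 with each array left out. For 4 h against 2 h the 62 became 97, 36, 11, 16 and 38 with array weights, 1 probe set per gene, adjusted p under 0.01, a log2 change of at least 1 and only the arrays compared, and 10 to 69 with each array left out. The 77 of the F test became 165 with array weights, 38 with 1 probe set per gene, 26 at adjusted p under 0.01, and 26 to 69 with each array left out. The overlap of 15 ran from 12 to 17. Lists called at 2 h, 4 h and between them were 2, 0 and 0 with an estimated correlation, and 2, 4 and 4 by fry. With each array left out they were 2 to 6, 4 to 6 and 4 to 8, with 2 at 2 h without control replicate 3. A stricter threshold can only lower a count. Fewer probe sets or arrays did not always do so: the 58 became 82 with dim probe sets left out and 155 without 4 h replicate 1. The cause was not tested for changes other than those of a stricter threshold.

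With the replicate number as a block, 130 probe sets were called at 4 h, 126 between 2 h and 4 h, 52 of them higher and 74 lower, and 124 by the F test. The numbers are not known to pair the 4 h arrays with the others. Same-numbered 4 h and control arrays had correlations of 0.25, 0.0049 and 0.13. For 4 h and 2 h arrays they were 0.23, 0.26 and 0.01. With the 2 h and control pairs included, 7 of 9 same-numbered correlations were over 0.1. The best partner had its own number for 8 of 9 arrays, as a hint from the data. The rise of SGK1 between 2 h and 4 h was the 1 call the block ended among those named, and at 2 h it changed no call. At 4 h the block added 8: EGR1, FOS, SERPINB2, DDIT3, DDIT4, GADD45B, PMAIP1 and GADD45A.

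Directions turned on another probe set for PLET1 (-0.0672 at 2 h, -0.22 at 4 h) and, among genes not called, for VRK3 (0.0158), TLR4 (0.21), INSIG1 (0.0661), CLDN3 (-0.10), COL5A1 (-0.0925 and -0.0121), DCN (-0.00725) and VWF (-0.0569 and -0.0369) at 2 h, and IFIT2 (0.13), PIGR (0.0580), SAA2 (-0.0364), HSPA8 (-0.10 and -0.18), SREBF2 (0.27 and 0.28), ARPC4 (-0.0014), TXNRD1 (-0.16), COL1A2 (-0.11), ITGAM (-0.0505) and CD53 (0.0766) at 4 h. SREBF2 also turned without control replicate 1 (0.0151). The cause was not tested. Some of the probe sets that turned were dim, such as that of DCN, but those of HSPA8 were bright.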

Other observations

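Probe sets of 1 chemokine disagreed, as seen after the values were examined. AMCF-II, a pig neutrophil chemokine, had 2 dim probe sets that rose at 4 h, by 1.39 ± 0.20 and 0.56 ± 0.08 (limma adjusted p = 0.0257 and 0.0243). Its brightest, which stood for the gene in the list, gave -0.05 ± 0.07. The dim ones had control means of only 2.98 and 2.76, and lay at percentiles 20.7 and 9.20 of mean level. The size of their rise is therefore uncertain. GBP1, an interferon-induced GTPase, had a dimmer probe set at 0.68 ± 0.11 at 4 h and its brightest at 0.26 ± 0.12.

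Genes of the glucocorticoid list went different ways at 4 h: SGK1 stood at 0.78 and CEBPD at 0.77 and TSC22D3 at -0.48, all past the threshold on their brightest probe set. The other probe sets of CEBPD gave 1.00, which passed, and 0.55, which did not, and that of TSC22D3 gave -0.13, which did not. Among the 124 control probe sets, 0 were called by limma in any comparison, and 8, 22 and 3 had an unadjusted p under 0.05 at 2 h, at 4 h and between them. Of the 23999 tested probe sets, 1538, 2978 and 2107 did so. The control probe sets with an unadjusted p under 0.01 at 4 h were all poly-A spikes, which are added before labelling. All of these were higher at 4 h than in the control, by 0.17 to 0.43.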
